A study of Mus musculus with 30 samples.

How the data were processed

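Total RNA of mouse hippocampus was measured on 30 single-colour Affymetrix MG-U74Av2 arrays, each holding 12488 probe sets. Per the labels, the pups came from a cross of C57BL/6 with Nf1 heterozygous animals, only males were used, 6 postnatal ages were sampled, and each sample pooled the hippocampi of 2 pups of 1 genotype. The labels gave genotype and age for every sample, and all 30 samples entered the comparisons. Wild-type groups held 3, 4, 2, 2, 2 and 2 samples at P10, P15, P18, P20, P28 and P32, and heterozygous groups held 4, 4, 2, 2, 2 and 1. Sample titles also carry a number and a letter, here called the title code, whose meaning is not given in the sources used here. Litter and processing day are not given in the sources used here, and p-values measure the spread between these pools. The number of arrays limits the precision of each comparison.

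The deposited values are intensities on a linear scale, 1 per probe set and array, as the authors processed them. The software that made them is not given in the sources used here. The mean of each array after leaving out 2% of the values at each end lay between 150.083 and 150.09, so the authors had brought all arrays to 1 level. No value was at or below 0 (0 values), and 6295 values (1.68%) lay below 1. Array medians lay between 49.99 and 59.11 with a median of 55.09, and the largest deviation of 1 median was 0.14 on the log2 scale. No further normalization was applied. Values below 1 were set to 1 and log2 was taken. Fold changes of dim probe sets depend on this floor and on the background correction of the authors' software.

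The platform annotation was used for gene names. Of the non-control probe sets, 10833 had 1 gene symbol, 396 had several and 1193 had none, and only those with 1 symbol were named. Entrez identifiers of 10817 of them matched the RefSeq gene table of GRCm38.p6, which gave current symbols and the gene coordinates printed here. These coordinates are those of the genes, not of the probes. The 66 control probe sets and the lowest 40% of the others by mean log2 over all arrays were left out, which removed 4969 probe sets below a mean log2 of 4.95 (an intensity of 30.8). The remaining 7453 probe sets were tested, of which 6762 had 1 symbol and together named 5694 genes.

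Tests used limma 3.58.1 in R 4.3.3 with statmod 1.5.0, with linear models fitted to all 30 samples, an intensity trend in the variance prior and two-sided p-values. The genotype effect over all ages came from a model with age and genotype. The other comparisons came from a model with 1 mean per genotype and age. These were the genotype effect at each age, its interaction with age (an F test), maturation (the mean of the P28 and P32 group means minus the P10 mean) in each genotype, the difference in maturation between genotypes, and each step between neighbouring ages averaged over genotypes. P-values were adjusted with the Benjamini-Hochberg method, and a probe set was called at an adjusted p below 0.05. Gene lists were tested with limma's camera at its preset correlation of 0.01 and again with a correlation estimated from the residuals, on 1 probe set per gene, the brightest on average. Of 30 lists of cell type markers and pathways, 26 had the 5 measured genes the test required. List scores are the mean log2 difference from the wild-type P10 mean over a list's genes. The tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined.

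The rule named the 12 called genes with the largest rise and the 12 with the largest fall in wild-type maturation, and the 3 of each for each step and each age. For the genotype effect over all ages it named the called genes or, with none, the 10 with the smallest p. For the interaction it named the 5 called genes with the smallest p, and for the difference in maturation 3 genes as not called. It added 2 to 4 members of each described list with the largest absolute change, and a set of genes of the nervous system, choroid plexus and blood named in advance. Lists given by their mean, count or test alone were not taken as described. Nf1 was reported whether or not it passed the filter, with a permutation test of genotype within age. The brightest probe set stood for a gene in lists and for genes named in advance, and the probe set with the smallest p elsewhere.

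The computations were tested on simulated data, with 200 of 7453 probe sets changed by a known amount. A log2 change of 0.5 was recovered for 92.5% of probe sets in the genotype effect over all ages, 44.8% at P10, 47.8% at P15, 14.9% at P18 and 5.97% at P32. A log2 change of 1 was recovered for 98.5%, 83.6%, 88.1%, 68.7% and 50.7% in the same comparisons. In wild-type maturation 37.3%, 83.6% and 100% of changes of 0.5, 1 and 2 were recovered. In the step from P10 to P15 these shares were 61.2%, 94.0% and 100%. False calls were 13 of 207 over all ages, 7 of 159 at P10, 9 of 165 at P15, 9 of 128 at P18 and 6 of 104 at P32. They were 6 of 153 in maturation and 6 of 176 in the step. The simulated noise was independent between probe sets, with the same spread in every group and the same genotype change at every age. Recovery in the real arrays, where groups such as heterozygous P18 varied more, can be lower.

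Alternatives were no filter, a filter on the lowest 60%, quantile normalization, log2(value + 32), a variance prior without trend, array weights, title codes or title numbers as blocks, a random block of group and title number, only the compared groups, and leaving out each library in turn. After the data were seen, the Gapdh 3'/5' log2 ratio of each array as a covariate and a fit of P10, P15, P28 and P32 alone were added, as was the difference between genotypes in each step. Principal components were taken over the tested probe sets. No column of per-sample values was left unused (0 columns).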

Results

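Expression of 12488 probe sets was measured in 30 pools of mouse hippocampus, 15 from wild-type males and 15 from males heterozygous for Nf1. Nf1 encodes neurofibromin, a GTPase-activating protein that turns Ras off. The pools covered P10, P15, P18, P20, P28 and P32 (days after birth), with 1 to 4 pools per genotype and age. After the authors' scaling, array medians lay between 49.99 and 59.11 intensity units. Within groups, log2 values of 2 libraries correlated across probe sets at 0.95 or more, except in the heterozygous P18 group, where the correlation was 0.93. P-values rest on the spread between pools of 2 pups, taken over all groups together.

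Nf1 (chromosome 11, 79339590 to 79581609, GRCm38.p6) was measured by 1 probe set and was dim in every library. Its intensity was 7.36 ± 4.92 (SD, n = 15) in wild type and 6.68 ± 4.31 (n = 15) in heterozygotes, with single values from 1.43 to 19.1. Its mean lay at the 13.5th percentile of all probe sets and below the filter. The genotype difference was -0.13 on the log2 scale (SE 0.35, 95% confidence interval -0.84 to 0.59), with a limma adjusted p of 0.943 and a two-sided permutation p of 0.738. The Nf1 level differed by 0.02 without the wild-type P20 library 2a, 0.01 after quantile normalization, 0.04 with the title codes as a block and 0.25 with the title number as a block, none of them called. Which part of Nf1 the probes read relative to the disrupted allele is not given in the sources used here, so this signal did not check the genotype labels.

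The comparison of wild-type P28 and P32 (n = 4) with P10 (n = 3) covered the longest span of the time course. Genes of myelin rose most. Mobp, a myelin protein, rose 27.5-fold, from 6.23 ± 0.40 (SD) to 11.01 ± 0.20 log2 units. Mog, a glycoprotein on the outer myelin surface, rose from 3.52 ± 0.92 to 8.49 ± 0.07 log2 units, a difference of 4.97 (SE 0.44). Its P10 level was dim, so the size depends on the floor, and with log2(value + 32) it was 3.14 and still called. Mal rose 19.5-fold, Cldn11, the tight junction protein of oligodendrocytes, 11.8-fold, Mag 7.84-fold and Mbp 4.68-fold. Genes of migrating and growing neurons fell. Dcx, a microtubule protein of immature neurons, fell by 2.36 on the log2 scale (SE 0.20), from 9.33 ± 0.09 to 6.97 ± 0.15 log2 units. Of the 7453 probe sets tested, limma called 2845 (38.2%), 1344 higher and 1501 lower, and 515 of them changed over 2-fold. On GRCm38.p6 Mog lies on chromosome 17 (37010740 to 37023398), Mbp on chromosome 18 (82475091 to 82585637) and Dcx on chromosome X (143855842 to 143933396).

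The myelin list had 15 measured genes, of which 14 rose and 0 fell, with a mean log2 fold change of 2.36 (camera adjusted p = 2.6e-13, adjusted p = 0.0382 with an estimated correlation). Of 16 astrocyte genes, 12 rose and 1 fell, with a mean of 0.74 (adjusted p = 2.3e-06, adjusted p = 0.0382 with an estimated correlation). Glul, which makes glutamine from glutamate, rose 5.68-fold, S100b had a log2 fold change of 1.68 and the gap junction gene Gjb6 one of 1.40. Among 31 genes of immature neurons and axon growth, 22 fell and 0 rose (mean -0.92, adjusted p = 3.8e-11, adjusted p = 0.0382 with an estimated correlation), led by Dpysl3 (-2.50), Cd24a (-2.36) and Dcx. Gap43, a protein of growth cones, fell by 1.08 on the log2 scale. Of 6 genes of the perineuronal matrix, 5 fell (mean -0.96, adjusted p = 0.00144, adjusted p = 0.0382 with an estimated correlation), among them Tnc (-1.52), Ncan (-1.37) and Bcan (-0.99).

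Of 14 genes of mural cells and meningeal fibroblasts, 8 fell (mean -0.58, adjusted p = 0.0031), with Col3a1 at -1.32, Rgs5 at -1.13 and Col1a1 at -1.11, but with adjusted p = 0.276 with an estimated correlation. Of 20 cell cycle genes, 6 fell (mean -0.50, adjusted p = 0.025), led by Cdc20 (-1.37) and Mcm5 (-1.12), with adjusted p = 0.276 with an estimated correlation. Col3a1 stood at -0.86 and Cdc20 at -0.88 with log2(value + 32), both still called. The call of the cell cycle list was also lost after quantile normalization (mean -0.39) and with the lowest 60% of probe sets left out (mean -0.23). Of 24 stress and chaperone genes, 12 rose and 2 fell (mean 0.23, adjusted p = 0.00874), with adjusted p = 0.284 with an estimated correlation. Its members went both ways, with Dnajb5, a heat shock protein 40 family member, at -2.46, Hspa1b at 1.25 and the metallothionein gene Mt1 at 1.19. Adjusted over the list alone, 14 myelin genes rose and 1 fell, 12 astrocyte genes rose and 1 fell, and 22 genes of immature neurons fell. Of the 26 lists, 7 were called at the preset correlation and 4 with an estimated one.

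Further large rises in wild-type maturation were log2 fold changes of 3.49 for Gsn, 3.03 for the neuregulin receptor gene Erbb3, 2.90 for Evi2a, which lies within an intron of Nf1, 2.81 for Nkx6-2, 2.50 for Kl and 2.46 for Septin4. The largest falls were log2 fold changes of -3.34 for Erdr1, -3.32 for Tmem129, -3.04 for Rac3 and -3.03 for Cacna1a, a calcium channel subunit. Fxyd7 (-2.93), Slc25a10 (-2.91), Mapk7 (-2.61), Wnt7b (-2.55) and Dnajb5 (-2.46) followed. With log2(value + 32), which shrinks changes of dim probe sets, all of these were still called, but Erbb3 stood at 1.94, Evi2a at 1.90, Nkx6-2 at 1.19 and Kl at 1.58. Cacna1a (-1.37), Slc25a10 (-1.37), Mapk7 (-1.34), Wnt7b (-1.04) and Dnajb5 (-1.11) also had smaller falls there. Of the genes named in advance, Gfap had a log2 fold change of 0.69 (adjusted p = 0.0122) and Grin2c one of 0.63 (adjusted p = 0.00769). The call of Gfap was lost without the wild-type P10 library 1b (0.56) or 2b (0.53), and that of Grin2c without 2b (0.53).

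Not called were Ttr (2.23, adjusted p = 0.0576), the NMDA receptor subunit gene Grin2b (-0.65, adjusted p = 0.053), Grin2a (-0.30), Camk2a (0.60), Syp (-0.13), Mki67 (0.01) and the globin genes Hba-a1 (-0.15), Hbb-b2 (0.20) and Hba-ps3 (0.13). Second probe sets did not always follow. The second probe sets of Mag (-0.80), Glul (-0.55) and Tmem129 (0.36) were called against the direction of the first, and those of Mbp (0.66) and Gfap (-0.07) showed smaller changes. Over all comparisons, 27 of 42 other probe sets of named genes had the same sign and 10 of those were also called. The plot of list scores by age shows the myelin and immature neuron genes in each library.

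**Figure D1:**
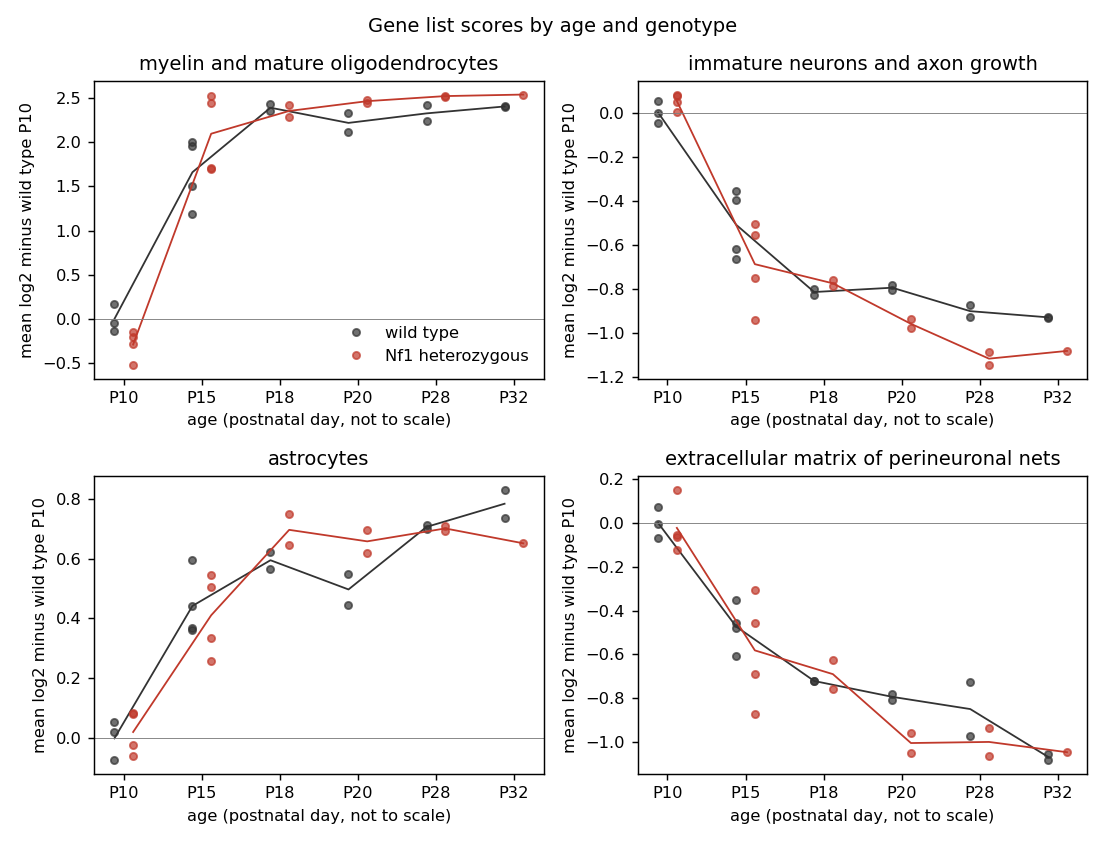
Scores of gene lists (mean log2 difference from the wild-type P10 mean, vertical axis) against age in days (horizontal axis), with 1 point per library and lines through the group means of each genotype. The wild-type myelin score rose from 0 at P10 to 1.66 at P15 and 2.40 at P32, and the immature neuron score was -0.93 at P32.

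Between P10 and P15 limma called 1932 probe sets, 932 higher and 1000 lower, over both genotypes (n = 8 at P15 and 7 at P10). Mog rose by a log2 fold change of 4.66 (SE 0.30), Mag by 3.53 (SE 0.19) and Mal by 3.30 (SE 0.31), while Adam28 (-1.83), Dcx (-1.82) and Cd24a (-1.80) fell. The second probe set of Mag stood at -0.42 and was not called (limma adjusted p = 0.0568). Mog was dim at P10 and stood at 2.52 with log2(value + 32), still called. Limma called 429 probe sets in wild type and 1577 in heterozygotes, and for the difference between them it called 0, with 505 at an unadjusted p below 0.05. Adam28 stood at -1.56 in wild type, where it was not called (adjusted p = 0.0586), and fell by 2.09 in heterozygotes. Of 15 myelin genes 13 rose (mean 2.02, adjusted p = 2.8e-21, adjusted p = 0.0157 with an estimated correlation), led by Mog and Mobp (4.11), and of 31 immature neuron genes 22 fell (mean -0.63, adjusted p = 4.1e-16, adjusted p = 0.0157 with an estimated correlation). Of 18 genes of synaptic vesicles and release 9 rose and 1 fell (mean 0.37), with Vamp1 at 2.67 and Nsf, which takes SNARE complexes apart, at 0.78. Vamp1 stood at 1.15 with log2(value + 32), still called, as was the microglial gene Cd53 at 0.43. Of 10 microglial genes 7 rose (mean 0.38), among them Cd53 (0.68), the protease gene Ctss (0.64) and C1qa (0.60). Among 16 immediate early genes 5 rose (mean 0.31), with Egr1 at 1.01, Fos at 0.94 and Nr4a1 at 0.88. Ribosomal protein genes fell in 14 of 20 cases (mean -0.23), with Rps19 at -0.50 and Rpl10a at -0.49, and cholesterol synthesis genes in 7 of 14 (mean -0.21), with Mvd and Fdps at -0.51 each. Cell cycle genes fell in 9 of 20 cases (mean -0.40), with Rrm2 at -0.78 (-0.45 with log2(value + 32), still called) and Cdc20 at -0.77.

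Also called in this step were the astrocyte (mean 0.42), stress (0.33), choroid plexus (0.84), voltage-gated channel (0.26) and perineuronal matrix (-0.52) lists. Of these 13 lists, 11 kept an adjusted p below 0.05 with an estimated correlation. The exceptions were choroid plexus (adjusted p = 0.333 with an estimated correlation) and voltage-gated channels (adjusted p = 0.116 with an estimated correlation). The step from P10 to P15 gave between 1623 and 2172 calls when single libraries were left out.

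Between P15 and P18 limma called 286 probe sets, 145 higher and 141 lower. Gabra2, a GABA receptor subunit, had a log2 fold change of 1.29 (SE 0.25), Ugt8a, which makes the myelin lipid galactosylceramide, one of 1.07 (SE 0.21) and Dmd one of 0.92 (SE 0.22). Erdr1 (-1.90), the actin-binding Cotl1 (-1.83) and 1 probe set of the cytoplasmic actin gene Actb (-1.56) were lower. The second probe set of Erdr1 stood at 0.05 (not called) and that of Actb at -1.46 (called). These values average genotypes that differed. Limma called 9 probe sets in wild type, 1590 in heterozygotes and 894 for the difference between them. Cotl1 stood at -0.51 in wild type and -3.14 in heterozygotes (adjusted p of the difference = 0.0387), and Actb at -0.50 and -2.61 (0.0161). The difference was not called for Gabra2 (0.68 and 1.90), Ugt8a (1.46 and 0.67), Dmd (0.75 and 1.10) or Erdr1 (-1.89 and -1.90). The myelin (mean 0.49), astrocyte (0.22), immature neuron (-0.20), mural (-0.19) and ribosomal (-0.14) lists were called at the preset correlation, with adjusted p = 0.535 with an estimated correlation for the first 4 and 0.543 for the ribosomal list. For the step P15 to P18, leaving out 1 library gave 118 calls (wild-type P15 2d), 27 (wild-type P18 1c), 16 (wild-type P18 1d), 71 (heterozygous P15 1d), 1587 (heterozygous P18 1a) or 21 (heterozygous P18 1b), and fitting only the compared groups gave 1. Without the heterozygous P18 library 1b the changes of Gabra2 (1.03), Ugt8a (0.99), Dmd (0.72), Erdr1 (-1.63) and Cotl1 (-0.91) were not called. Nor were those of Ugt8a (1.05), Dmd (0.94) and Erdr1 (-2.05) without wild-type P18 1c, of Gabra2 (1.18), Ugt8a (1.09), Dmd (0.91), Erdr1 (-1.75) and Cotl1 (-1.44) without wild-type P18 1d, and of Erdr1 (-1.80) without heterozygous P15 1d. Actb stood at -0.86 without heterozygous P18 1b and Cotl1 at -2.74 without 1a, both called. Dmd (0.48) and Cotl1 (-0.74) were still called with log2(value + 32). With array weights Actb alone of these 6 genes was called, and with the compared groups only none was. With the Gapdh 3'/5' ratio as a covariate Ugt8a (0.96), Dmd (0.78), Erdr1 (-1.94) and Cotl1 were not called.

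The later steps rested on fewer libraries. Between P18 and P20 only Erdr1 was called (2.99, SE 0.50), and its second probe set stood at -0.25. Erdr1 changed by 4.16 in wild type and stood at 1.82 in heterozygotes (adjusted p of the difference = 0.188), and 107 other probe sets were called for a difference between the genotypes. Wild-type titles carry the number 2 at P20 and 1 at P18 and P28, while heterozygous titles carry 1 at each of these ages. Title number therefore cannot be told apart from age in wild type in this step, or from genotype in the difference. The interferon list was called at the preset correlation (mean 0.31, adjusted p = 9.5e-04, adjusted p = 0.48 with an estimated correlation). The call of Erdr1 was lost without wild-type P18 1d (2.84), wild-type P20 2a (3.04) or 2b (2.94), heterozygous P18 1b (2.72) or heterozygous P20 1a (3.07) or 1b (2.91). It was also lost without the trend in the variance prior, with array weights and with the Gapdh ratio as a covariate (adjusted p = 0.0835, 0.126 and 0.0595). The step P18 to P20 had 423 calls without heterozygous P18 1a, 3 without wild-type P18 1c or heterozygous P15 1d, and 2 without wild-type P15 2d or either wild-type P28 library. It had 0 without wild-type P18 1d, either wild-type P20 library or either heterozygous P20 library.

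Between P20 and P28 limma called 601 probe sets, 228 higher and 373 lower, with Anp32a (1.76), the kinase gene Wnk1 (1.71) and Pnmt (1.45) highest and Cacna1a (-2.30), St6galnac6 (-2.16) and Ywhag (-1.96) lowest. The other probe sets of Anp32a (-0.01), Ywhag (0.21), Wnk1 (0.46 and 0.22) and Pnmt (-0.31) were not called, and camera called 0 of 26 lists. Here too the values average both genotypes, with 495 probe sets called in wild type, 54 in heterozygotes and 43 for the difference. As in the step before, title number changed in wild type alone. It cannot be told apart from age in wild type, or from genotype in the difference. Anp32a stood at 0.02 in wild type and 3.50 in heterozygotes (adjusted p of the difference = 0.0112), and Ywhag at -3.18 and -0.74 (0.0443). The difference was not called for Wnk1 (3.09 and 0.33, 0.132), Cacna1a (-3.03 and -1.57), St6galnac6 (-3.44 and -0.87) or Pnmt (1.21 and 1.68). For the step P20 to P28, leaving out 1 library gave 265 calls (wild-type P20 2a), 262 (wild-type P20 2b), 382 (wild-type P28 1a), 315 (wild-type P28 1b), 954 (heterozygous P18 1a), 951 (heterozygous P18 1b), 156 (heterozygous P20 1b) or 148 (heterozygous P28 1a). Without heterozygous P28 1a the changes of Cacna1a (-1.46), St6galnac6 (-1.61), Wnk1 (1.62) and Pnmt (1.60) were not called. Wnk1 also lost its call without wild-type P20 2b (1.62), wild-type P28 1a (1.63) or heterozygous P20 1a (1.52), and St6galnac6 without wild-type P20 2b (-2.09), wild-type P28 1a (-1.70) or heterozygous P20 1b (-2.02). Pnmt also lost it without either wild-type P20 library (2b 1.39), wild-type P28 1a (1.37) or 1b (1.52), heterozygous P20 1b (1.05) or heterozygous P28 1b (1.29). With log2(value + 32) Pnmt (0.70, adjusted p = 0.0573) was not called, and Wnk1 (0.95), Cacna1a (-0.87) and St6galnac6 (-1.23) were. With the Gapdh ratio as a covariate Wnk1 (1.23) was not called and St6galnac6 stood at -1.41, still called, and with the compared groups only Cacna1a was not called (adjusted p = 0.0621).

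Between P28 and P32 only Ndufa3, a subunit of respiratory complex I, was called (-1.33, SE 0.21), and its second probe set stood at -0.04. It stood at -0.33 in wild type and -2.32 in heterozygotes, with 1 heterozygous library at P32 (adjusted p of the difference = 0.242). It was not called without the heterozygous P32 library (-0.33), wild-type P28 1b (-1.28), wild-type P32 1a (-1.32) or heterozygous P28 1b (-1.25), nor with log2(value + 32) (-0.67, adjusted p = 0.282) or the compared groups only (adjusted p = 0.121). The step P28 to P32 had 5 calls without the first of these and 0 without any of the other 3. The microglial (mean 0.14, adjusted p = 0.428 with an estimated correlation) and hippocampal neuron (mean -0.19, adjusted p = 0.169 with an estimated correlation) lists were called in that step at the preset correlation.

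The same maturation contrast in heterozygotes asked whether development ran alike. Heterozygous P28 and P32 libraries (n = 3) against P10 (n = 4) gave log2 fold changes of 5.91 for Mobp and 4.74 for Mal, and of -2.89 for Dpysl3, -2.88 for Dcx and -2.87 for Cd24a. Mog, with a mean of 2.48 log2 units at P10, had a difference of 6.15 (SE 0.45) whose size depends on the floor, and with log2(value + 32) it was 3.48 and still called. Limma called 2718 probe sets, 1265 higher and 1453 lower. Across probe sets, which are not independent replicates, the changes of both genotypes correlated (Pearson r = 0.833, Spearman rho = 0.806, slope 0.85). The calls shared 960 rises, where independent lists would share 228, and 988 falls, where they would share 293, and 3 probe sets were called in opposite directions. Of 3612 probe sets called in either genotype, 3469 had the same sign in both. These contrasts have no library in common.

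In heterozygotes 14 of 15 myelin genes rose (mean 2.82, adjusted p = 0.041 with an estimated correlation), 12 of 16 astrocyte genes rose (mean 0.65, 0.0452), 26 of 31 immature neuron genes fell (mean -1.15, 0.0313) and 5 of 6 matrix genes fell (0.0448). The mural list (mean -0.53, adjusted p = 0.26 with an estimated correlation) and the cell cycle list (mean -0.66, adjusted p = 0.0842 with an estimated correlation) were called at the preset correlation alone. So were the immediate early (0.40, adjusted p = 0.247 with an estimated correlation), stress (0.15, adjusted p = 0.416 with an estimated correlation) and ribosomal (-0.24, adjusted p = 0.496 with an estimated correlation) lists.

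For the difference itself limma called 0 probe sets, with 508 at an unadjusted p below 0.05 where 373 would be expected by chance. The smallest p-values belonged to Ndufa3 (-1.62, SE 0.29, adjusted p = 0.0584), Peg3 (-1.56, SE 0.30, adjusted p = 0.0844) and Adk (-0.92, SE 0.19, adjusted p = 0.0844). Other probe sets of Ndufa3 (-0.03) and Peg3 (-0.23 and -0.39) were not called. The single heterozygous P32 library weighs as much here as the P28 group. The genotype difference of Ndufa3 was -0.22 at P28 and -2.21 at P32, and that of Peg3 -0.61 and -1.75. At the preset correlation the myelin list differed by 0.45 (adjusted p = 6.1e-04), the immature neuron list by -0.24 (adjusted p = 2.5e-04) and the immediate early list by 0.25 (adjusted p = 0.0313), with adjusted p = 0.575 with an estimated correlation for each. For the difference in maturation between genotypes, leaving out 1 library gave 1 call (wild-type P10 1b), 2 (wild-type P10 2a, wild-type P15 1a, heterozygous P15 1d or 2c) or 3 (heterozygous P18 1a or 1b), and fitting only the compared groups gave 6.

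The genotype effect over all ages, the average heterozygous minus wild-type difference within age (n = 15 and 15), was small. No gene was called, and the smallest p-values belonged to the ubiquitin ligase gene Rnf167 (-0.40, SE 0.09), Ndrg1 (0.29, SE 0.06), Sqle, an enzyme of cholesterol synthesis (-0.27, SE 0.06), and 6330403K07Rik (-0.41, SE 0.09), each with a limma adjusted p of 0.142. Serf1 (-0.27), Mrpl15 (0.20), the dopamine receptor gene Drd2 (-0.55), AI506816 (-0.37), Mrpl48 (0.18) and Pip4k2a (0.23) followed, each with an adjusted p of 0.268. Limma called 0 probe sets and 698 had an unadjusted p below 0.05, where 373 would be expected by chance. Genes named in advance were not called, with Gap43 at -0.28, Grin2c at 0.22, Dcx at -0.16, Mbp at 0.14, Ttr at 0.35 and Gfap at -0.08.

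No member of any list was called for genotype over all ages. At the preset correlation 4 lists shifted, with means of -0.10 for immature neurons (adjusted p = 0.00269), 0.12 for myelin (0.0147), 0.11 for hippocampal pyramidal and granule neurons (0.0147) and 0.04 for stress and chaperones (0.0147). With an estimated correlation 0 were called by camera, with adjusted p = 0.384 for immature neurons, 0.47 for myelin, 0.384 for hippocampal neurons and 0.384 for stress. Adjusted over the list alone, 2 genes of synaptic vesicles were higher and 2 of cholesterol synthesis lower. The 27 measured genes of the Ras and MAP kinase pathway had a mean difference of 0.02 (adjusted p = 0.479), the 8 MAP kinase target genes one of -8.7e-05 (adjusted p = 0.88) and the 34 neighbours of Nf1 on chromosome 11 one of -0.03 (adjusted p = 0.479). The count of 4 lists was 1 without the wild-type P15 library 2d, 2 without the heterozygous P15 library 2c and 1 without the heterozygous P32 library. The myelin list lost its call without wild-type P15 2c (0.07) or 2d (0.09), heterozygous P15 2c (0.08) or 2d (0.07) or heterozygous P32 (0.12). Hippocampal neurons lost theirs without wild-type P15 2d, wild-type P18 1d or heterozygous P32 (0.09 each), and stress genes without wild-type P15 2d (0.02), heterozygous P15 2c (0.02) or heterozygous P32 (0.03).

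Within single ages, few genes passed the test at P10, P15, P28 and P32. At P10 (n = 4 heterozygous and 3 wild type), Degs2, which makes phytoceramides, was higher by 1.97 (SE 0.28), the RNA editing gene Adar by 1.58 (SE 0.28) and the transcription factor gene Zic2 was at -1.23 (SE 0.22). Degs2 lies on chromosome 12 (108686792 to 108702306). The other probe set of Adar stood at 0.19 and was not called. The genotype effect at P10 had 0 calls without wild-type 2b, with Degs2 at 1.71, Adar at 1.42 and Zic2 at -1.15, and 1 without heterozygous 2a, with Adar at 1.64 and Zic2 at -1.27. Adar also lost its call without wild-type 1b (1.57) or heterozygous 1b (1.57) or 2b (1.46), and Zic2 without wild-type 1b (-1.30) or 2a (-1.25) or heterozygous 1a (-1.22) or 2b (-1.16). With the title codes as a block none of the 3 genes was called (adjusted p = 0.253 each), nor was any with the compared groups only (0.175 for Degs2, 0.278 for Adar and Zic2). With log2(value + 32) Adar (0.65, adjusted p = 0.106) and Zic2 (-0.62, adjusted p = 0.0817) were not called, and Degs2 (1.10) was. With the title number as a block Adar (adjusted p = 0.0665) and Zic2 (0.0976) were not called. Among lists, myelin had a mean of -0.29 (adjusted p = 0.0156, adjusted p = 0.944 with an estimated correlation) and an exact permutation p of 0.0571, where 0.0286 is the smallest possible. Choroid plexus genes had a mean of 0.53 (adjusted p = 0.0116, adjusted p = 0.944 with an estimated correlation) and an exact permutation p of 0.4.

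At P15 (n = 4 and 4) limma called 0 probe sets, with 440 at an unadjusted p below 0.05. The myelin list was higher in heterozygotes by 0.44 (adjusted p = 9.8e-09), with adjusted p = 0.375 with an estimated correlation, and its scores of 2.09 ± 0.45 and 1.66 ± 0.39 (SD) gave an exact two-sided permutation p of 0.229. The difference was -0.27 among libraries with title number 1 and 1.14 among those with number 2, with 2 libraries per genotype in each. The immature neuron (-0.18), stress (0.10) and ribosomal (-0.09) lists were called at the preset correlation, with adjusted p = 0.375, 0.375 and 0.505 with an estimated correlation. With the title codes as a block the genotype effect at P15 had 120 calls. That fit held only libraries 2c and 2d of each genotype at P15, which are those with title number 2.

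At P28 (n = 2 and 2) Qdpr, which recycles the cofactor tetrahydrobiopterin and belongs to the myelin list, was higher in heterozygotes by 0.95 (SE 0.14, limma adjusted p = 0.00579). It was not called without the wild-type library 1b (0.87) or without either heterozygous library (0.95). For the genotype effect at P28, 8 probe sets were called without the wild-type library 1a, 2 without 1b and 0 without either heterozygous library. The endothelial (0.29), microglial (0.23), immature neuron (-0.22) and myelin (0.20) lists were called at the preset correlation, with adjusted p = 0.222, 0.397, 0.397 and 0.748 with an estimated correlation.

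At P32 the heterozygous group had 1 library, taken to vary like the other groups, so each value sets that library against 2 wild-type ones with no replicate of its own. It was higher in Wnt7b (2.14, SE 0.41) and lower in Ndufa3 (-2.21, SE 0.32), the imprinted gene Peg3 (-1.75, SE 0.34) and the water channel gene Aqp4 (-1.46, SE 0.28). Second probe sets of Ndufa3 (0.09) and Peg3 (-0.27 and -0.52) were not called, nor was that of Aqp4 (-1.14, adjusted p = 0.157), which had the sign of the first. The genotype effect at P32 had 1 call in place of 4 without any 1 library of P10, of heterozygous P20 or of heterozygous P28, or without wild-type P32 1a or heterozygous P15 1c or 2d. It was 7 without wild-type P15 1a, 2c or 2d or heterozygous P18 1a, 12 without heterozygous P18 1b and 15 without wild-type P32 1b. The calls of Wnt7b, Peg3 and Aqp4 (adjusted p = 0.049 each) were lost, at 2.14, -1.75 and -1.46, without any 1 of the listed P10, heterozygous P15, P20 and P28 libraries, and at 1.69, -1.68 and -1.41 without wild-type P32 1a. Peg3 (-1.82) and Aqp4 (-1.51) also lost theirs without wild-type P32 1b, and Wnt7b (2.14) without either wild-type P18 library or heterozygous P15 1d or 2c. None of the 4 genes was called with log2(value + 32), with Wnt7b at 0.73 (adjusted p = 0.400) and Ndufa3 at -1.03, Peg3 at -1.60 and Aqp4 at -1.28 (adjusted p = 0.0577 each). Wnt7b, Peg3 and Aqp4 were not called without the filter, after quantile normalization or with the title number as a block either, nor were Peg3 and Aqp4 with the lowest 60% left out or without the trend in the variance prior. Wnt7b was also not called with the title codes as a block (2.60) or the compared groups only. The hippocampal neuron (0.31) and immediate early (0.34) lists were called at the preset correlation, with adjusted p = 0.19 with an estimated correlation for both.

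At P18 (n = 2 and 2) heterozygotes differed from wild type in many genes. Wnk1 was higher by 3.19 on the log2 scale (SE 0.62), Xrn1, an RNA exonuclease, by 2.60 (SE 0.66) and Nexmif by 2.25 (SE 0.36). The folate receptor gene Folr1 stood at -3.44 (SE 0.88), another probe set of Actb at -3.37 (SE 0.46) and Cotl1 at -2.88 (SE 0.67). These SEs come from the spread over all groups, not from the P18 libraries alone. In heterozygotes the SD at P18 (n = 2) was 1.81 for Wnk1, 0.36 for Xrn1 and 0.72 for Nexmif, against 0.16, 0.46 and 0.31 in wild type. It was 0.97 for Folr1, 1.71 for Actb and 2.59 for Cotl1, against 0.26, 0.11 and 1.08. Folr1 belongs to the choroid plexus list, whose score was 0.52 ± 0.05 in heterozygotes and 1.46 ± 0.21 in wild type (SD, n = 2 each; camera adjusted p = 0.262). Wnk1 lies on chromosome 6 (119923969 to 120038695) and Actb on chromosome 5 (142903115 to 142907976). The other probe sets of Wnk1 stood at 2.44 (called) and 0.27 (not called), and that of Actb at -2.25 (called). Limma called 1700 probe sets, 822 higher and 878 lower, with 2747 at an unadjusted p below 0.05. Of 20 ribosomal protein genes 7 were lower and 2 higher, with Rps29 at -1.60, Rpsa at -0.64 and Rps27 at -0.62, and 4 of 10 microglial genes were lower, among them C1qa (-0.84), C1qc (-0.83) and C1qb (-0.82). Of 16 astrocyte genes 4 were higher and 4 lower, with Glul at 1.29, Slc4a4 at 0.87, Aqp4 at 0.74 and Clu at -0.73. The other probe set of Aqp4, the one named at P32, stood at 0.07 and was not called. Of 15 hippocampal neuron genes 4 were higher, with Neurod6 at 0.86, Ccn3 at 0.67 and Zbtb20 at 0.64. Rps29 stood at -0.85 with log2(value + 32), still called. Camera called 0 of 26 lists, and 0 of 15 myelin genes passed the test. The microglial score was 0.44 in heterozygous 1a and 0.04 in 1b, against 0.51 and 0.57 in wild type. Without heterozygous 1b, 0 microglial and 0 hippocampal neuron genes were called, with C1qa at -0.31, C1qc at -0.46, C1qb at -0.52, Neurod6 at 0.66, Ccn3 at 0.46 and Zbtb20 at 0.33. In that setting 1 astrocyte gene was higher (Glul, 1.16) and 1 ribosomal gene lower (Rps27, -0.63). Slc4a4 (0.44), Aqp4 (0.36), Clu (-0.47), Rps29 (-1.19) and Rpsa (-0.33) were not called there. C1qa, C1qc and Neurod6 were not called without wild-type 1c (-0.74, -0.80 and 1.11) or 1d (-0.94, -0.86 and 0.61) either. Slc4a4 (1.07), Aqp4 (0.60) and Ccn3 (0.42) also lost their calls without wild-type 1c, and Slc4a4 (0.67), Clu (-0.64) and Zbtb20 (0.35) without 1d.

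The calls at P18 moved with single libraries and when an RNA measure was added to the model. The genotype effect at P18 had 820 calls without wild-type library 1c, 556 without 1d, 2769 without heterozygous library 1a and 264 without 1b, and it was 0 when only these 4 libraries were fitted, with 1366 at an unadjusted p below 0.05. It was 204 with array weights and 80 with the Gapdh 3'/5' ratio as a covariate. This ratio was higher in both heterozygous libraries than in both wild-type ones. Calls lost with the covariate therefore do not tell RNA integrity from a genotype effect. Without heterozygous 1b Wnk1 (1.91), Xrn1 (2.34), Folr1 (-2.76) and Cotl1 (-1.05) were not called, nor were Xrn1 (2.27) and Cotl1 (-2.11) without wild-type 1c or Folr1 (-3.26) without wild-type 1d. With the covariate Wnk1 (1.59), Xrn1 (2.20), Nexmif (1.52), Folr1 (-2.71) and Cotl1 (-0.37) were not called, and Actb was, at -1.69. Actb stood at -2.16 without heterozygous 1b and Cotl1 at -4.71 without 1a, both called. With array weights Xrn1 and Folr1 were not called (adjusted p = 0.154 and 0.169). The values of Wnk1 (1.90), Xrn1 (1.17), Nexmif (1.49), Folr1 (-2.20) and Cotl1 (-1.05) were smaller with log2(value + 32), and all 5 genes were still called. The Gapdh 3'/5' ratio on the log2 scale was -0.26 and -0.23 in the wild-type P18 libraries and -0.05 and 0.48 in the heterozygous ones, and the Actb 3'/5' ratio of the heterozygous library 1b was 1.14. The plot of these ratios shows every library.

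**Figure D2:**
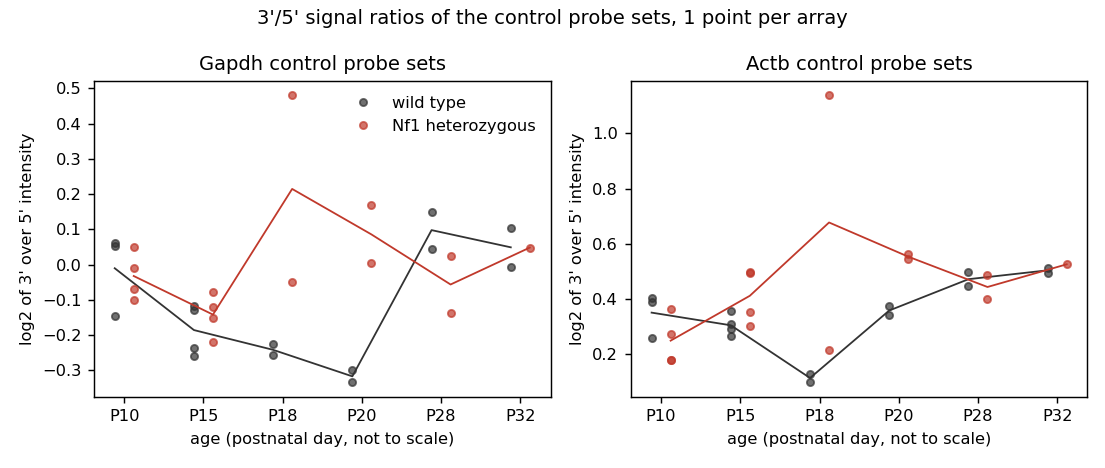
Log2 of the 3'/5' probe set ratio of Gapdh and of Actb (vertical axes) for each library against age in days (horizontal axis), by genotype. The heterozygous P18 library 1b had the highest values, 0.48 for Gapdh and 1.14 for Actb.

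At P20 (n = 2 and 2) the lipase gene Pla2g4f was higher in heterozygotes by 2.87 (SE 0.47), Wnk1 by 2.74 (SE 0.62) and the transcription factor gene Crx by 2.40 (SE 0.50). Anp32a (-3.37, SE 0.41), Actb (-3.33, SE 0.46) and Dnajb5 (-3.28, SE 0.77) were lower. The other probe set of Anp32a stood at 0.19 and was not called, whereas that of Actb stood at -2.93 and was called. Those of Wnk1 stood at 1.69 and 0.13 and were not called. Limma called 169 probe sets, 67 higher and 102 lower. Among 31 immature neuron genes Sox11 (1.21) was higher and Dpysl3 (-1.35) and Gap43 (-1.03) lower, and camera called 0 of 26 lists. None of these 3 genes was called without wild-type 2a (1.22, -1.26 and -0.90), wild-type 2b (1.21, -1.43 and -1.16) or heterozygous 1a (1.18, -1.29 and -0.81), nor were Sox11 (1.24) and Dpysl3 (-1.41) without heterozygous 1b. Of 16 astrocyte genes 2 were higher, Aqp4 (1.03) and Glul (0.90), and 0 lower (list adjusted p = 0.44). The other probe set of Aqp4 stood at 0.75 and was not called. Of 20 ribosomal protein genes 2 were higher, Rps10 (0.94) and Rpl19 (0.45), and 0 lower (mean 0.14, list adjusted p = 0.108), against a mean of -0.21 at P18. Rpl13a stood at 0.45 and was not called. Aqp4 and Glul were not called without wild-type 2a (0.82 and 0.75) or heterozygous 1a (0.75 and 0.37), nor was Glul without wild-type 2b (1.05). Rpl19 was not called without any 1 of these libraries (0.46, 0.44, 0.49 and 0.40), and Rps10 was called without each. The Gapdh 3'/5' ratio on the log2 scale was -0.33 and -0.30 in wild type and 0.00 and 0.17 in heterozygotes. Here too it parted the genotypes, so calls lost with the ratio as a covariate do not tell RNA integrity from a genotype effect.

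The genotype effect at P20 had 22 calls without wild-type P20 library 2a, 29 without 2b, 77 without heterozygous P20 library 1a, 87 without 1b, 348 without heterozygous P18 library 1a and 349 without 1b. It was 95 without the filter, 387 with array weights and 43 with the Gapdh ratio as a covariate, under which Pla2g4f (2.22), Wnk1 (1.34), Crx (2.11) and Dnajb5 (-1.03) were not called and Actb (-1.85) was. The calls of Wnk1, Crx and Dnajb5 were also lost without wild-type P20 2a (2.91, 2.50 and -3.33), 2b (2.58, 2.31 and -3.24) or heterozygous P20 1b (2.36, 2.28 and -3.32), and that of Dnajb5 without heterozygous P20 1a (-3.24). With log2(value + 32) Wnk1 (1.41) and Crx (0.88) were not called, and Pla2g4f (1.34) and Dnajb5 (-1.79) were. At P20 both wild-type titles carry the number 2 and both heterozygous titles the number 1, so title number and genotype cannot be told apart there. At P18 all titles carry the number 1. No title code was shared by both genotypes at P18 or P20, while each other age had a shared code.

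**Figure D3:**
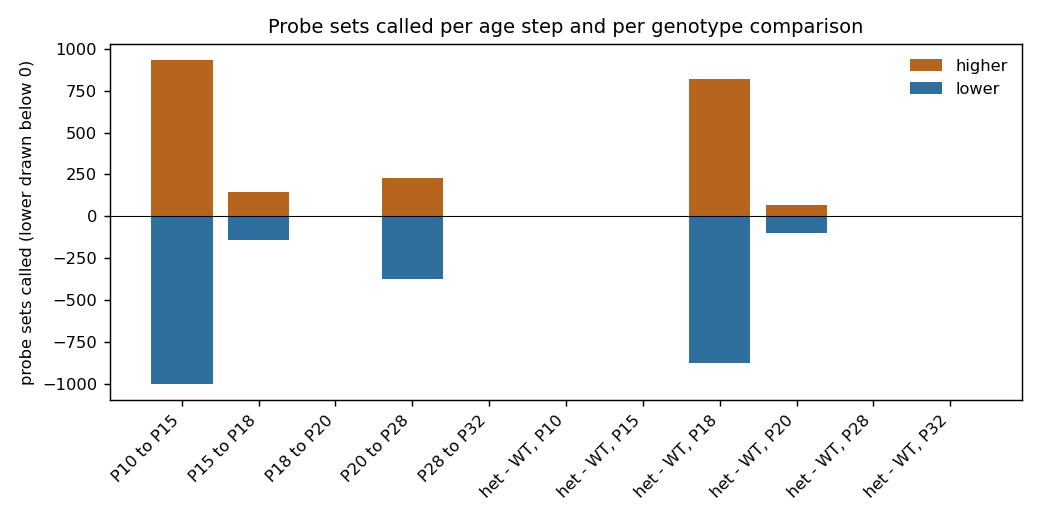
Number of probe sets called by limma at an adjusted p below 0.05 in each age step and in the genotype effect at each age. Vertical bars start at 0, with higher drawn above 0 and lower below it. The step P10 to P15 had 1932 calls, the genotype effect at P18 1700 and that at P20 169.

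The genotype differences at P18 and P20 were set side by side. The calls shared 87 probe sets in the same direction, 25 higher where independent lists would share 7.39 and 62 lower where they would share 12, and 3 were called in opposite directions. The log2 fold changes of both ages, which have no library in common, correlated at 0.34 across probe sets, which are not independent replicates. At P28 the sign was the same for 567 of the 1700 probe sets called at P18 and for 43 of the 169 called at P20.

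An F test asked whether the genotype difference varied with age. Limma called 484 probe sets, led by Actb (adjusted p = 7.0e-04), Ndufa3 (0.00108), the nucleolar gene Ncl (0.00108), Nexmif (0.00137) and the AMPA receptor subunit gene Gria1 (0.00167). Actb differed by -3.37 at P18 and -3.33 at P20, against -0.26 at P10 and 0.77 at P28. In wild type this Actb probe set stood at 9.37 and 9.44 log2 units at P18 and P20 and at 6.93 at P28. In heterozygotes it stood at 6.01 and 6.12 at P18 and P20 and at 7.69 at P28, so both genotypes changed after P20. Ncl differed by 1.61 at P18 and the called probe set of Gria1 by -0.91 at both P18 and P20. The brightest probe set of Gria1 stood at 0.48 at P18 and 0.77 at P20 and was not called. None of the 26 lists was called for the interaction (0 lists, smallest adjusted p = 0.443).

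The genotype by age interaction had 104 calls in place of 484 without wild-type P18 library 1c, 95 without 1d, 242 without wild-type P20 library 2a, 247 without 2b, 1818 without heterozygous P18 library 1a, 197 without 1b and 287 without heterozygous P28 library 1b. It had 3 over P10, P15, P28 and P32 alone, where Actb, Ncl, Nexmif and Gria1 were not called (adjusted p = 0.63, 0.78, 0.47 and 0.53), and 22 with the Gapdh ratio as a covariate, where Nexmif (adjusted p = 0.0656) and Gria1 (0.0945) were not called. With the title codes as a block, which holds no P18 or P20 library, none of the 5 was called (adjusted p = 0.0705 for Actb, 0.0826 for Ndufa3, 0.575 for Ncl, 0.184 for Nexmif and 0.496 for Gria1). Ndufa3 had 0.0116 without the heterozygous P32 library. The plot of principal components shows where each library stood.

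**Figure D4:**
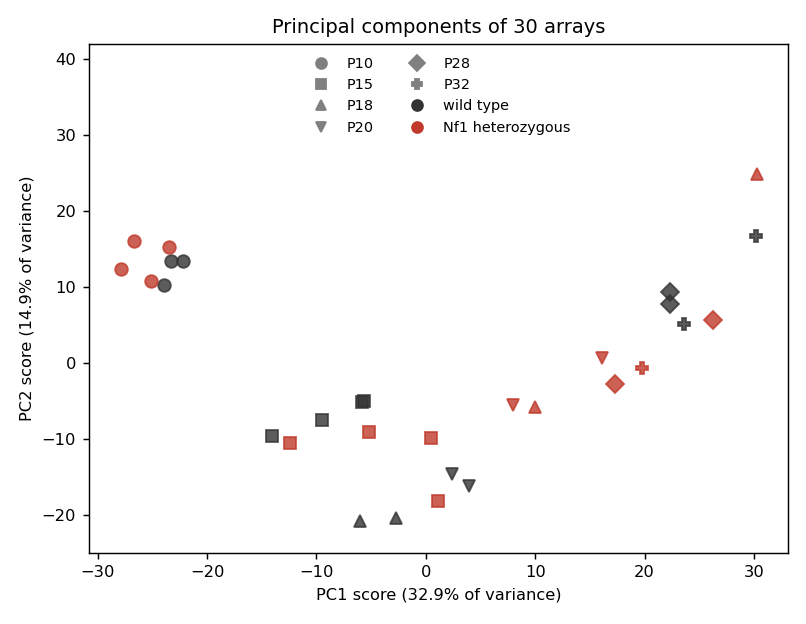
First and second principal components of the tested probe sets, which held 32.9% and 14.9% of the variance, with 1 point per library by age and genotype.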

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

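The test that left out the heterozygous P18 library 1b, the correlations with wild-type change, the positions on the wild-type axis at P18 and P20, the difference between genotypes in each step, the Gapdh 3'/5' ratio as a covariate and the fit of P10, P15, P28 and P32 alone were chosen after the results were seen.

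The genotype difference varied with age in 484 probe sets, led by Actb, which was lower in heterozygotes at P18 and P20, where 87 probe sets were called in the same direction. Leaving out the heterozygous P18 library 1b left 1 heterozygous library at P18, and the bounds for that test were set after its result. The test therefore could not decide whether 1 divergent library made the difference. RNA integrity or labelling is a candidate explanation, since the P20 difference correlated at 0.312 across probe sets with that between the heterozygous P18 libraries 1b and 1a, but these also lay apart on the wild-type maturation axis (1.01 and 0.65), and a ratio of 0.498 between correlations of probe sets of 1 gene at P18 and in maturation decided nothing. Earlier maturation is another, since every heterozygous library lay beyond every wild-type one on that axis at P18 (wild type 0.44 and 0.39) and P20 (0.78 and 0.63 against 0.52 and 0.54), but the differences correlated at 0.525 and 0.353 with later wild-type change, 0.412 and 0.241 with all of wild-type maturation and -0.122 and -0.0362 with change from P10 to P15, and of 4 comparisons of myelin and immature neuron scores only the 2 at P20 were met, with P18 immature neuron scores of -0.76 and -0.79 in heterozygotes against -0.83 and -0.80. The Gapdh ratio was also higher in wild type at P28 and P32 (0.10 and 0.05) than at P18 and P20 (-0.24 and -0.32). In wild type it was -0.01 at P10 and -0.19 at P15, so it did not rise steadily with age. RNA integrity, maturation and a direct effect of genotype stay open. Title number and genotype cannot be told apart at P20, and no title code was shared by both genotypes at P18 or P20.

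The myelin list was higher in heterozygotes at P15 by 0.44, with an exact p of 0.229. The developmental stage of single pools may account for it. The position of the 8 libraries on the wild-type maturation axis, computed without the genes of the myelin list, correlated with their myelin score (Pearson r = 0.838, permutation p = 0.0115, Spearman rho = 0.738, permutation p = 0.0459). That axis kept other genes with large rises in wild-type maturation, such as Erbb3 (3.03) and Nkx6-2 (2.81). Oligodendrocyte content alone could move both measures, so the correlation does not separate it from stage. Without the 2 libraries farthest from the median position r was 0.732, and this was 1 relation tested. The position was 0.41 ± 0.11 in heterozygotes and 0.33 ± 0.06 in wild type (SD, n = 4 each, exact p = 0.2), so an effect of genotype on stage stays open. With 2 libraries of each genotype per title number at P15, a shift of a number common to both genotypes cancels in the difference. The test of title number was void, because the design fixes the mean of the differences within number at 0.435. The difference was -0.27 within number 1 and 1.14 within number 2, so an effect of title number that differed between genotypes stays open.

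One library stood apart in its group: the heterozygous P15 library 2d had the lowest second principal component, -18.15, by Dixon's criterion. That was 1 of 99 tests of 33 measures in 3 groups, and chance marks about 1 in 20.

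The genes below were named because their difference at 1 age was large and called, so the interaction test on the same libraries partly restates that choice. For these, the test of interaction with age gave limma adjusted p-values of 0.0162 for Degs2 and 0.0126 for Adar, named at P10, and 0.0916 for Zic2, which was not called. Those named at P18 had 0.00693 (Wnk1), 0.0279 (Xrn1), 0.00137 (Nexmif) and 7.02e-04 (Actb), while Folr1 (0.116) and Cotl1 (0.0847) were not called. At P20 they were 0.021 (Pla2g4f), 0.0289 (Crx), 0.00545 (Anp32a) and 0.0404 (Dnajb5), and at P28 0.00787 (Qdpr). At P32, where heterozygotes had 1 library, they were 0.00787 (Wnt7b), 0.00108 (Ndufa3), 0.0025 (Peg3) and 0.0101 (Aqp4). Ncl and Gria1, named for the interaction itself, had 0.00108 and 0.00167. The change differed between genotypes in 894 probe sets for the step P15 to P18, 107 for P18 to P20 and 43 for P20 to P28. Among named genes the adjusted p of that difference was 0.0387 for Cotl1 and 0.0161 for Actb in the first of these and 0.0112 for Anp32a and 0.0443 for Ywhag in the last. In the steps into and out of P20 title number changed in wild type alone, so title number and genotype cannot be told apart there.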

How the results depend on the processing

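The Gapdh 3'/5' ratio as a covariate and the fit of P10, P15, P28 and P32 only were chosen after the results were seen. The counts for maturation in wild type, maturation in Nf1 heterozygotes and step P10 to P15 stayed within 1.5 times under all alternatives run, with 2270 to 3074, 2195 to 3033 and 1623 to 2172 calls when single libraries were left out. The genotype effect over all ages had 0 limma calls under every alternative run. Of the alternative values for named genes, 4051 kept direction and side of the threshold, 205 lost the call, 40 gained it and 42 reversed. For lists these were 397, 24, 0 and 0. The number of named-gene values that kept direction and side is no measure of robustness. Many settings left out a library outside the compared groups, where the difference at 1 age cannot move. Genes that were not called also count as kept when they stayed so. Dim probe sets near the floor limit what the arrays could show, Nf1 among them. Where a count or sign moved, the cause was not tested, except that fewer samples or probe sets were fitted in some settings.

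For the genotype effect at P10 (3 calls) there were 7 with no filter, 0 with the lowest 60% left out, 7 after quantile normalization, 1 with log2(value + 32), 5 with eBayes without trend, 10 with array weights, 1 with the replicate block, 1 with title number as a block, and 0 to 4 without single libraries. None of the 3 named genes was called with the replicate block or with the compared groups only, where the 2 calls were other probe sets. For the genotype effect at P15 (0 limma calls, 440 at unadjusted p below 0.05) there were 120 with the replicate block, 1 with the covariate and 0 without any single library. At P15 the replicate block held only 2 libraries of each genotype, all of title number 2. At 1700 calls, the genotype effect at P18 had 204 with array weights, 0 with the compared groups only, where 1366 had an unadjusted p below 0.05, 80 with the covariate and 264 to 2769 without single libraries. At 169 calls, the genotype effect at P20 had 95 with no filter, 387 with array weights, 43 with the covariate and 22 to 349 without single libraries.

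The genotype effect at P28 (1) had 2 with no filter, 4 with the replicate block, 4 with the compared groups only and 0 to 8 without single libraries. The genotype effect at P32 (4) had 1 with no filter, 0 with the lowest 60% left out, 1 after quantile normalization, 0 with log2(value + 32), 2 with eBayes without trend, 11 with array weights, 94 with the replicate block, 1 with title number as a block, 94 with the compared groups only, 7 with the covariate and 1 to 15 without single libraries. The genotype by age interaction (484) had 284 with array weights, 36 with the replicate block, 256 with title number as a block, 22 with the covariate, 3 over ages P10, P15, P28 and P32 only, and 95 to 1818 without single libraries. The difference in maturation between genotypes (0) had 1 with eBayes without trend, 4 with array weights, 6 with the replicate block, 1 with group and title number as random block, 6 with the compared groups only, 2 with the covariate and 0 to 3 without single libraries.

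The step P15 to P18 (286) had 129 with no filter, 3 with array weights, 1 with the compared groups only, 55 with the covariate and 16 to 1587 without single libraries. The step P18 to P20 (1) had 2 with the lowest 60% left out, 2 after quantile normalization, 0 with eBayes without trend, 0 with array weights, 2 with the random block, 2 with the compared groups only, 0 with the covariate and 0 to 423 without single libraries. The step P20 to P28 (601) had 1116 with array weights, 343 with the covariate and 148 to 954 without single libraries. The step P28 to P32 (1) had 0 with the lowest 60% left out, 0 with log2(value + 32), 0 with the compared groups only and 0 to 5 without single libraries. For gene lists in maturation (7), an estimated correlation left 4, and 7 to 10 were called without single libraries. For gene lists in genotype (4) it left 0, array weights 1, the replicate block gave 7, and 1 to 6 were called without single libraries.

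The Nf1 level (-0.13) reversed to 0.011 after quantile normalization, 0.038 with the replicate block and 0.25 with title number as a block, and ran from -0.30 to 0.025 without single libraries. Signs of genes that were not called reversed as follows. Mki67 in maturation in wild type went to -0.0026 with title number as a block, -0.077 with the covariate, and ran from -0.14 to 0.17 without single libraries. For the genotype effect over all ages, Gfap went to 0.052 (replicate block), 0.032 (covariate) and 0.0082 (ages P10, P15, P28 and P32 only). Grin2b went to 0.041 (quantile), 0.033 (weights), 0.23 (replicate block), 0.11 (title number), 0.18 (covariate), 0.27 (those ages only), and ran from -0.078 to 0.084 without single libraries. Hba-a1 went to 0.039 (weights), 0.0014 (replicate block) and 0.0022 (covariate), and ran from -0.12 to 0.013 without single libraries. Syp went to 0.0024 (weights), 0.11 (replicate block), 0.077 (title number), 0.11 (covariate) and 0.13 (those ages only), and ran from -0.058 to 0.068 without single libraries.

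Title codes shared by both genotypes at P10 and P15 did not pair the samples: their deviations from the group means correlated at -0.04, 0.13 and 0.03 at P10 and -0.18 and -0.11 at P15. The codes shared at P28 and P32 were not tested in this way. The replicate block used the 16 samples with a shared code and gave no value for the genotype effects at P18 and P20, maturation within a genotype or the steps. Title number as a block gave none at P20, and leaving out the only heterozygous P32 library gave none for the genotype effect at P32. A library left alone in its group was assumed to vary like the other groups. The random block had a consensus correlation of -0.03, and array weights ran from 0.265 to 2.02. Both heterozygous P18 libraries had the lowest weight.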

Other observations

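The splits of the steps P15 to P18, P18 to P20 and P28 to P32 in the model of all groups were chosen after the results were seen. Several lists were not called in wild-type maturation although single members were. Of 17 voltage-gated channel genes 4 rose and 4 fell, with Cacna1a at -3.03, Scn1a at 1.11 and Kcnab2 at 1.07 (list adjusted p = 0.864). Of 17 glutamate receptor and postsynaptic genes 3 rose and 3 fell, with Grik5 at -1.72 and Dlg1 at 0.88 (0.988), and their mean of -0.09 and median of -0.30 opposed the direction of the test. Of 8 GABA and glycine receptor genes 3 rose, among them Gabra2 (1.55) and Glrb (0.52), and 0 fell (0.509). Of 15 endothelial genes 2 rose and 6 fell, with Tie1 at -1.78, Eng at -1.47 and Abcb1a at 1.12 (0.137). With log2(value + 32) Cacna1a stood at -1.37, Tie1 at -1.02 and Abcb1a at 0.62, all still called. Of 27 Ras and MAP kinase pathway genes 7 rose and 6 fell, with Map2k1 at 1.47, Rasgrf1 at 1.33 and Gab1 at 1.04 (0.556).

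Of 18 synaptic vesicle genes 5 rose and 4 fell, with Vamp1 at 1.19 and Stx1a at -1.10 (adjusted p = 0.693), and Vamp1 was not called with log2(value + 32) (0.32). Of 15 interneuron genes 2 rose and 5 fell, with Vip at 1.22 (not called), Reln at -0.96 and Gad1 at 0.90 (0.693). Of 13 interferon genes 5 rose, with Ifi27 at 1.23 and Gbp3 at 0.998 or, with log2(value + 32), 0.64 (list adjusted p = 0.0938), and of 14 cholesterol synthesis genes 1 rose and 6 fell, with Mvd at -1.20 and Nsdhl at -0.91 (0.0938). Of 20 ribosomal protein genes 7 fell and 2 rose, with Rplp0 at -0.93 and Rpl10a at -0.79 (0.0862). Of 34 genes neighbouring Nf1 on chromosome 11, 5 rose and 8 fell, with Evi2a at 2.38 and Traf4 at -1.58 (0.938). That list shares Evi2a with the myelin list. The hippocampal neuron (0.864), thalamus (0.693), MAP kinase target (0.693), immediate early (0.56), cAMP (0.693) and respiratory chain (0.693) lists were not called either, and the genes furthest from 0 in the hippocampal list were Man1a (1.41) and Neurod1 (-1.14).

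Markers of choroid plexus varied between pools. Of 8 choroid plexus genes 3 rose and 1 fell in wild-type maturation, with Kl at 2.50 (1.58 with log2(value + 32)), Ttr at 2.23 (not called) and Car14 at 0.94 (adjusted p = 0.137). Ttr, which is abundant in choroid plexus, stood at 9.83, 6.01 and 8.53 log2 units in the wild-type P10 libraries 1b, 2a and 2b. Of 10 microglial genes 2 rose and 1 fell, with Ctss at 1.22, Cd53 at 0.95 (0.60 with log2(value + 32)) and Cx3cr1 at -0.75 (adjusted p = 0.359). The lists of oligodendrocyte precursors (3 measured genes), blood (3), liver (1) and striatum (3) were too small to test. Among the precursors Pdgfra stood at -0.88 and Sox10 at 0.45 in wild-type maturation.

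Other splits of the same samples tested whether the counts could arise by chance, fitted on the compared groups except for the genotype effect over all ages and the interaction. Maturation, steps and single ages were fitted as plain comparisons of 2 sets of libraries, the steps without a genotype term, so their counts differ from those of the model of all groups. The real split, which is counted in each share, had the largest count in 4 comparisons. These were maturation in wild type (2819 calls, 1 of 35 splits as large, highest other 1) and in heterozygotes (3252, 1 of 35, highest other 1). The others were the step P10 to P15 (2095, 1 of 100, highest other 237) and the step P20 to P28 (210, 1 of 35, highest other 10). All other splits stayed far below these counts, but 35 splits allow no share smaller than 1 of 35. For the interaction (484) 2 of 100 splits were as large, and for the unadjusted count of the difference in maturation (782) 4 of 100. Both shares were under 0.05, but other splits gave 498 and 964. No share in this paragraph was adjusted for the number of split tests. Chance is not excluded for the interaction or the difference in maturation.

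Chance cannot be excluded for the genotype effect over all ages (698 at an unadjusted p below 0.05, 12 of 100 splits as large, highest other 1204), the genotype effect at P10 (2 calls, 4 of 35, highest other 4) or the genotype effect at P15 (375 unadjusted, 15 of 35, highest other 1096). The split at P15 with 1096 set wild-type 1a and 1b with heterozygous 2c and 2d against the rest, which is a structure of the samples other than genotype. For the steps P15 to P18 (100 of 100, highest other 1), P18 to P20 (35 of 35, highest other 279) and P28 to P32 (35 of 35, highest other 1) the plain comparison gave 0 calls, so every split was as large by construction and nothing follows about chance. The split with 279 parted wild type from heterozygotes over P18 and P20.

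These 3 steps were split again with ages exchanged within genotype in the model of all groups. For the step P15 to P18 (286 calls) 4 of 100 splits were as large, a share under 0.05 that was not adjusted for the number of split tests. Another split gave 604, so chance is not excluded in that model. That split put wild-type P15 1a and 1b and heterozygous P15 2c in place of 3 of the P18 libraries, which is a structure of the samples other than age. For the step P18 to P20 (1 call) 12 of 36 were as large, highest other 219, so chance cannot be excluded. The step P28 to P32 (1 call) had 9 of 18 as large, highest other 3, and 18 splits are too few for a share under 0.05.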
